A study of Mus musculus with 9 samples.

How the data were processed

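Gene expression was measured by RNA sequencing in 9 libraries of 4T1-TGL cells, 3 each of Ctrl, KO1 and KO2. Per the labels, the authors named HISAT and RSEM and the genome builds mm10 and GRCm38, without versions. The deposited tables give, per library and gene, an expected count, which is an estimated count that the authors did not normalise. They also give FPKM, which the authors scaled by transcript length and library size. Before use it was checked that FPKM times length over the expected count was nearly constant within a library. Only genes with an FPKM of at least 0.01 were listed, so a gene not listed in a library was taken as 0. The tables held 19072 gene identifiers, of which 17719 were Entrez numbers and 1351 were unnamed models of the provider, and 13541 were listed in all 9 libraries. Symbols of 26 genes had been turned into dates in the tables and were read from the identifiers instead. Positions came from a RefSeq table of the same build, GRCm38, which held 17682 of the numeric identifiers. Of the expected counts in a library, between 74.7% and 75.8% were whole numbers, and all were rounded to whole numbers for the tests.

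Samples were grouped by their titles. The design text of the record orders the sixth and ninth samples differently from the titles, and Malat1 levels were not used to decide. Totals per library ran from 30655924 to 35406395. Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, estimateDisp, robust quasi-likelihood fit and F test), with all 9 libraries in 1 fit, 1 coefficient per group and 6 residual degrees of freedom. The filter left 13682 genes, the TMM factors ran from 0.95 to 1.036 and the common biological coefficient of variation was 11.1%. The contrasts were KO1 against Ctrl, KO2 against Ctrl, KO2 against KO1 and the mean of both clones against Ctrl. P-values were adjusted by Benjamini and Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. A gene was shared when called in both clones in the same direction. CPM are after TMM scaling, and the principal components used log2 CPM with a prior count of 2.

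For a gene with 0 counts over a group, the fold is a lower bound against a floor of 3 counts over the group plus the counts that the listing minimum could hide. For 1 to 3 counts, the ratio is given with an exact conditional binomial interval at 95%. The genes named were set by a rule. It took Malat1 and its tested neighbours, Serpinb6b, Gsdmd, Casp1, Ctsg, Cd274 and B2m; the 10 genes per direction with the largest shared change of at least 2-fold; the 5 per direction with the largest difference between the clones; and up to 4 members per list, with 5 CPM as the minimum in the shared and clone parts. Unnamed models were left out. The rule takes 161 genes, of which 128 are printed with a value, and the others are covered by the counts per list; Ctsg was listed in no library.

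A total of 32 gene lists were written from general knowledge, and the 27 with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. They cover the Malat1 neighbours, Wnt ligands and targets, serpins, pyroptosis, MHC class I presentation, interferon-stimulated genes, checkpoint ligands, inflammatory genes, epithelial, mesenchymal, matrix and stem or basal genes, the cell cycle, nuclear speckles and paraspeckles, YAP/TEAD, glycolysis, cholesterol, ATF4, NRF2 and p53 targets, ribosomal proteins, mitochondrially encoded, imprinted and cancer-testis genes, and markers of fibroblasts, macrophages, T and NK cells, endothelium and adipocytes. The grouping, tests, lists, rule for named genes and alternatives were fixed before the data were examined. The theme of the study, pyroptosis and T cell killing, was known by then. Serpinb6b, Gsdmd, Casp1, Ctsg, Cd274 and B2m were named for that reason, and the choice of lists may follow that theme as well.

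The alternatives were DESeq2 size factors in edgeR, upper quartile and total count scaling, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), limma on log2(FPKM + 1) and on log2(FPKM + 0.1), only the 2 groups compared, a replicate block, each library left out in turn, an adjusted p of 0.01, and a minimum change of 2-fold. In these, lists were tested by camera on the gene statistics. Whether replicate numbers pair the samples was checked on the deviations of each library from its group. Libraries with the same number had correlations from -0.34 to 0.05 across genes, so the samples were treated as unpaired. Those with different numbers ran from -0.17 (Ctrl replicate 3 and KO1 replicate 1) to 0.34 (Ctrl replicate 2 and KO1 replicate 1). Ctrl replicate 1 and KO1 replicate 2 had 0.24. A factor shared by such libraries across groups was neither tested nor modelled.

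The steps were tested on simulated data with 13396 genes and 50 changed genes per fold size. EdgeR recovered 60% of genes changed 1.5-fold in the KO1 layout and 64% in that of KO2, 90% and 88% at 2-fold, 100% at 4-fold, and 98% and 100% at 8-fold. False calls were 14 of 188 and 14 of 190 calls (7.4% each). A planted list was called and 0 of 26 others were. Genes were drawn independently of each other there, so the list test was not tried on correlated genes. Far fewer genes were changed than were called in these data, so the rates may not carry over. Shared calls were compared with 20 simulated data sets without effects. Tables were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.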

Results

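RNA from cultured 4T1-TGL cells, a derivative of the 4T1 mouse breast cancer line of BALB/c origin, was sequenced in 9 libraries. Of these, 3 were from cells with intact Malat1 (Ctrl), 3 from a first Malat1 knockout line (KO1) and 3 from a second one (KO2), each measured in cells grown in DMEM/F12. The knockout lines are called clones here, although the labels do not use that word. The tables held expected counts per gene, with totals per library between 30655924 (KO2 replicate 2) and 35406395 (Ctrl replicate 2). Between 16104 and 16254 genes were listed in the control libraries, between 16295 and 16488 in KO1, and between 15100 and 15678 in KO2. The first principal component carried 66.3% of the variance and set the KO2 libraries apart from the other 6. The second carried 21.2% and separated Ctrl from KO1. On the first, the sixth and ninth samples lay with their titled groups. KO1 replicate 3 was at -46.48 (others -48.2 and -41.05) and KO2 replicate 3 at 92.24 (others 92.58 and 88.5), which argues against a swap between them. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Pairs of replicates differed by more than counting noise, with a chi-square per gene between 8.27 and 60.74, and none was counted as a duplicate.

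The first question was how much of the targeted transcript each clone had lost. Malat1, an abundant nuclear long noncoding RNA (gene 72289, chromosome 19, 5795690 to 5802672, GRCm38), was at 462 ± 54.9 CPM in Ctrl (SD, n = 3). In KO1 it was at 3.40 ± 0.669 CPM (SD, n = 3), or 0.735% of the control, and in KO2 at 126 ± 31.5 CPM (SD, n = 3), or 27.2%. The log2 fold changes were -7.08 ± 0.236 in KO1 (SE; edgeR adjusted p = 2.55e-08) and -1.88 ± 0.178 in KO2 (SE; edgeR adjusted p = 1.37e-05). Each SE was back-calculated as the size of the log2 fold change over the square root of its F statistic, and is approximate. Single KO2 libraries ranged from 21.2% to 34.6% of the control mean. The values are totals per gene and do not show which part of the transcript the remaining reads came from.

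Of the 17 tested neighbours of Malat1, 12 were higher and 2 lower in KO2, and 4 were higher and 1 lower in KO1. Of all tested genes, 54.1% were called in KO2 and 30.5% in KO1. The block of 50 genes on chromosome 19 that spans Malat1 had a median log2 fold change of 0.367 in KO2 and 0.042 in KO1. The listed neighbours were not tested apart from that block. Neat1, the long noncoding RNA at the core of paraspeckles, rose in KO2 from 901 ± 109 to 1900 ± 300.1 CPM (SD, n = 3), a log2 fold change of 1.08 (edgeR adjusted p = 2.58e-05). Its log2 fold change in KO1 was 0.18 (edgeR adjusted p = 0.30). Ltbp3, which encodes a binding protein of latent TGF-beta, rose in both clones (log2 fold change 0.61 in KO1 and 1.49 in KO2), as did Slc25a45 (0.56 and 1.35). In KO2, Frmd8 also rose (0.90), while Cdc42ep2 (-1.07) and the NF-kB subunit gene Rela (-0.46) fell. The neighbours were called as a list in KO2 (camera adjusted p = 0.00429), and the call was lost with an estimated correlation (adjusted p = 0.271). Tested between the clones, the list was higher in KO2 (camera adjusted p = 0.0393), which was also lost with an estimated correlation (adjusted p = 0.43). The counts adjusted over the list alone were 12 and 2 in KO2 and 4 and 2 in KO1. With only Ctrl and KO1 in the fit, 3 neighbours were called in KO1 in place of 5.

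**Figure D1:**
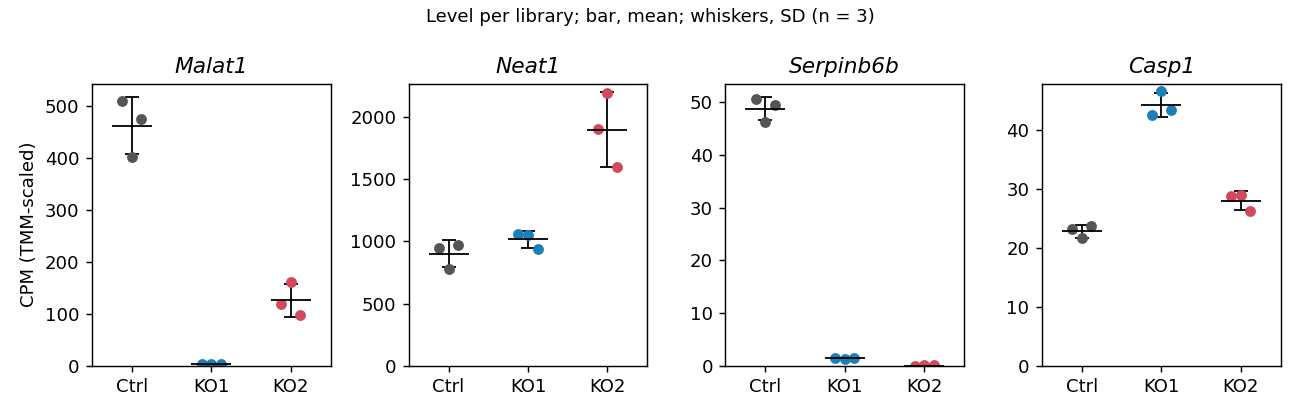
Level of Malat1, Neat1, Serpinb6b and Casp1 in each library, in CPM after TMM scaling (vertical axis, linear from 0), for Ctrl, KO1 and KO2. Points are libraries, bars are means and whiskers SD (n = 3). Malat1 stood at 0.735% of the control in KO1 and at 27.2% in KO2.

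The comparison of KO1 with Ctrl asked which genes differed in the clone with the least Malat1. Among the lists, protease inhibitors of the serpin family were the clearest group, with 13 of 19 tested members lower and 1 higher. Serpinb6b, an intracellular serine protease inhibitor, fell from 48.8 ± 2.20 to 1.41 ± 0.0702 CPM (SD, n = 3; chromosome 13, 32956811 to 32979067), which is 2.90% of the control (95% counting interval 2.44% to 3.43%). Sulf2, an extracellular sulfatase that edits heparan sulfate, rose from 8.42 ± 1.03 to 68.9 ± 3.02 CPM (SD, n = 3; log2 fold change 3.03). Inflammatory genes moved both ways, since Icam1, the adhesion ligand of leukocyte integrins, fell (log2 fold change -4.16) while the chemokine gene Cx3cl1 rose (2.08). In all, edgeR called 4177 of 13682 tested genes, 2136 higher and 2041 lower, at an adjusted p under 0.05. Of these, 1083 changed at least 2-fold (602 higher and 481 lower).

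Among the serpins in KO1, Serpina3g fell by 8.50 on the log2 scale (edgeR adjusted p = 9.41e-10). Serpina1b was left with 1 count in KO1, 0.0517% of the control (95% counting interval 0.00131% to 0.288%). Serpina3f had 0 counts and was at least 224-fold lower than in Ctrl, where it stood at 9.13 ± 0.871 CPM (SD, n = 3). Serpine2, which encodes protease nexin-1, was the member that rose (log2 fold change 1.18). The Serpina1 and Serpina3 genes are near-identical copies whose reads the counting could split, so the values of single members are uncertain. The list passed the test (camera adjusted p = 5.98e-21) and also passed it with an estimated correlation (adjusted p = 0.00113). Of the members lower in both clones, Serpina1a, Serpina1b, Serpina3f, Serpina3g and Serpina3h lie close together on chromosome 12. The list tests may thus count linked genes as separate. Counts of 1 and 13 were also found when adjusted over the list alone.

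Of the 49 tested interferon-stimulated genes, 19 were higher and 0 lower in KO1 (camera adjusted p = 0.0038). The call was lost with an estimated correlation (adjusted p = 0.90). Adjusted over the list alone, 20 were higher and 0 lower, while 5644 genes in all had an unadjusted p under 0.05. Trim30a, an interferon-induced TRIM family gene, rose the most among the named members (log2 fold change 2.14), followed by the guanylate-binding protein gene Gbp4 (0.80) and Socs1, a feedback inhibitor of cytokine signalling (0.51). The count fell to 11 without Ctrl replicate 1, to 10 without Ctrl replicate 3 and to 10 without KO1 replicate 1. Of the 33 tested inflammatory cytokines and NF-kB targets, 9 were higher and 13 lower in KO1, with lower levels of the acute-phase gene Saa3 (log2 fold change -1.20), the chemokine gene Cxcl16 (-1.12) and Csf3, which encodes G-CSF (-0.80). Of the 23 checkpoint and NK or T cell ligands, 6 were higher and 6 lower, including lower Ptgs2 (-1.93), Tgfb2 (-0.93) and Nectin2 (-0.46). Among the 28 genes of MHC class I presentation, 6 were higher and 0 lower, with Tapbp at 0.38, and 3 were called without Ctrl replicate 3. B2m, the light chain of MHC class I, had a log2 fold change of 0.21 that did not pass (edgeR adjusted p = 0.0675), but passed without Ctrl replicate 2 (0.27) and without KO1 replicate 1 (0.29). The log2 fold change of the checkpoint ligand gene Cd274 was 0.26 (edgeR adjusted p = 0.349). When adjusted over the list alone, the counts were 9 and 13, 6 and 8, and 6 and 0 for these last 3 lists, none of which camera on counts called. Camera on the gene statistics called the MHC list as higher only without Ctrl replicate 2 (adjusted p = 0.0139).

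The study concerns pyroptosis, a lytic cell death driven by inflammasomes and gasdermins. Of the 24 tested genes of that list, 8 were higher and 5 lower in KO1, and camera did not call it. The median log2 fold change was 0.03 and the mean -0.25, so the signs of median and mean differed. Casp1, the inflammasome protease, rose from 22.8 ± 1.09 to 44.2 ± 2.11 CPM (SD, n = 3; log2 fold change 0.95, edgeR adjusted p = 5.55e-06). The sensor genes Nlrp3 (-5.19), Nod2 (-2.23), Naip6 (-2.99) and Naip5 (-1.71) fell; Naip5 and Naip6 are close copies and their split is uncertain. Gsdmd, which encodes the pore-forming gasdermin D, had a log2 fold change of -0.09 (edgeR adjusted p = 0.39). With p adjusted over the list alone, 9 were higher and 5 lower.

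Wnt ligands and targets also moved both ways in KO1. Of 11 tested ligands, 4 were higher and 4 lower, with Wnt7b higher (log2 fold change 0.56). Wnt9b had 0 counts in KO1 and was at least 24.8-fold lower, and Wnt3 kept 2 counts, 1.58% of the control (95% counting interval 0.189% to 5.83%). Wnt6 fell by 3.93 on the log2 scale, and the value was -4.67 without KO1 replicate 1. The median over the ligands was 0.26 and the mean -1.16. That mean includes the fitted value of Wnt9b, which depends on the prior count. Of 12 targets of the pathway, 2 were higher and 5 lower, among them higher Tnfrsf19 (1.17) and Sfrp1, a secreted Wnt antagonist (1.69), and lower Tcf7 (-0.90). Neither list was called by camera, and the counts were unchanged when adjusted over the list alone.

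Epithelial genes in KO1 included 6 higher and 2 lower of 18 tested, with the simple epithelial keratin genes Krt18 (log2 fold change 0.94) and Krt8 (0.77) and the protease gene Prss8 (0.97) among the higher ones. Of 23 mesenchymal genes, 4 were higher and 6 lower, including lower Mmp9 (-1.87), Mmp13 (-1.51), Tagln (-2.69) and Acta2 (-2.97). Of 37 matrix and basement membrane genes, 13 were higher and 5 lower, with Timp2 (0.58), Col7a1 (0.86) and Col18a1 (0.59) higher and decorin, Dcn, lower (-1.26). The median of that list was 0.14 and the mean -0.08. Of 25 stem and basal genes, 8 were higher and 10 lower, with Lgr6 higher (1.38) and Ly6a, which encodes Sca-1, lower (-3.07). Krt17 fell by 4.76 on the log2 scale, and the value was -5.55 without KO1 replicate 3, while Krt14 kept 1 count, 0.767% of the control (95% counting interval 0.0193% to 4.35%). Of 24 YAP/TEAD targets, 7 were higher and 8 lower, including higher Itgb2 (0.87) and lower Arhgef17 (-1.03) and Ankrd1 (-1.09). Camera called none of these 5 lists. Fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes, passed 4 of them (fry adjusted p = 0.00768 for the epithelial list, higher, and 0.0032, 0.0161 and 0.00278 for the mesenchymal, stem and basal, and YAP/TEAD lists, lower). In KO1, fry passed 11 of the 27 tested lists, and 27 when changes in either direction counted. In that order, and adjusted over the list alone, the counts were 7 and 2, 4 and 7, 13 and 6, 9 and 11, and 8 and 10.

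Camera on counts called none of the cell cycle, splicing and metabolic lists in KO1. Camera on the gene statistics called the G2/M list as higher (adjusted p = 0.0164), but not without Ctrl replicate 2 (adjusted p = 0.179), without KO1 replicate 2 (adjusted p = 0.184) or with DESeq2 (adjusted p = 0.0941). It called the G1/S and cholesterol lists as lower only without Ctrl replicate 2 (adjusted p = 0.0125 and 0.0139) and without KO1 replicate 2 (adjusted p = 0.0128 and 0.0359). Of 40 G2/M genes, 9 were higher and 0 lower, with Kif23 (log2 fold change 0.61), Top2a (0.43), Cdc25c (0.40) and Nusap1 (0.31), and 14 were called without KO1 replicate 1. Of 39 G1/S and S phase genes, 2 were higher and 6 lower, with Rfc4 at 0.32 and Blm (-0.43), Ccne1 (-0.85) and Ccne2 (-0.69) lower, and the total was 13 without KO1 replicate 2 and 5 without KO1 replicate 3. Of 38 nuclear speckle and splicing factor genes, 1 was higher and 5 lower (3 in all without Ctrl replicate 3). Of 16 paraspeckle genes, 0 were higher and 3 lower (1 without Ctrl replicate 1 or without KO1 replicate 3). Of 35 glycolysis and hypoxia genes, 2 were higher and 3 lower, with Aldoc at 2.61 and Ddit4 at -0.73; the total was 3 without Ctrl replicate 1, KO1 replicate 1 or KO1 replicate 3, and 9 without KO1 replicate 2. The median of that list was -0.07 and the mean 0.02. Of 24 cholesterol synthesis genes, 1 was higher and 4 lower, with Sqle at 0.58 and Hsd17b7 at -1.09 (9 in all without Ctrl replicate 2). Of 32 ATF4 and unfolded protein response genes, 2 were higher and 6 lower, with Chac1 at -0.64 and Stc2 left with 1 count, 0.313% of the control (95% counting interval 0.0079% to 1.76%). That total was 5 without Ctrl replicate 1, Ctrl replicate 3 or KO1 replicate 3. Of 26 NRF2 antioxidant genes, 3 were higher and 7 lower, with Gstm1 at 0.93, Taldo1 at -0.48 and the heme oxygenase gene Hmox1 at -0.71. Of 20 p53 targets, 1 was higher and 3 lower, including Mdm2 at -0.35. Of 67 ribosomal protein genes, 4 were higher and 7 lower, with totals of 7 without Ctrl replicate 2, 6 without Ctrl replicate 3, 17 without KO1 replicate 2 and 7 without KO1 replicate 3. The corresponding counts adjusted over the list alone were 7 and 0 (G2/M), 2 and 5 (G1/S), 1 and 3 (speckle), 0 and 3 (paraspeckle), 2 and 3 (glycolysis), 1 and 3 (cholesterol), 2 and 4 (ATF4), 3 and 7 (NRF2), 1 and 2 (p53) and 3 and 5 (ribosomal).

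Markers of other cell types and of the germline were mostly not detected or too low to test. In KO1, 1 of 5 tested fibroblast markers was higher (Pi16, log2 fold change 1.84) and 2 were lower, and 1 of 5 macrophage and neutrophil markers was higher (Cd68, 0.89). The median of the macrophage list was -0.04 and the mean 1.22. That mean includes the fitted value of Lyz2, with 0 counts in Ctrl, which depends on the prior count. The macrophage total was 2 without Ctrl replicate 1 and without each KO2 replicate in turn. Of 3 endothelial markers, 2 were lower, Plvap (-1.80) and Eng (-0.41), with a list median of -0.41 and a mean of 0.10, and of 2 adipocyte markers Fabp4 was higher (3.14). The 1 tested T and NK cell marker, Lck, was not called. Among 9 imprinted and X-inactivation genes, 2 were higher and 1, Eif2s3x, was lower (-0.33). Of 4 cancer-testis genes, 1 was higher, and this total fell to 0 without Ctrl replicate 1 or 2, KO1 replicate 1 or 2, or KO2 replicate 1 or 3. None of the 13 mitochondrially encoded genes was listed. For these lists, the counts adjusted over the list alone were 1 and 2 (fibroblast), 2 and 0 (macrophage), 1 and 2 (endothelial), 1 and 0 (adipocyte), 0 and 0 (T and NK), 2 and 1 (imprinted) and 2 and 0 (cancer-testis). Camera called neither the fibroblast, the macrophage nor the imprinted list, and the others were too small for it.

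The comparison of KO2 with Ctrl asked the same of the clone that kept more Malat1. Inflammatory mediators were lower almost throughout, with 28 of 33 tested cytokines and NF-kB targets lower and 2 higher. Saa3 fell from 42.6 ± 1.33 to 0.0558 ± 0.0190 CPM (SD, n = 3; log2 fold change -9.48), and Csf3 from 120 ± 4.65 to 10.6 ± 0.539 CPM (SD, n = 3; -3.50). Interferon-stimulated genes were lower in 42 of 49 cases and higher in 2. Serpins were lower in 15 of 19 cases and higher in 1, and Serpinb6b kept 2 counts, 0.0459% of the control (95% counting interval 0.00556% to 0.166%). Morc1, a germline gene that silences transposons, had 0 counts in Ctrl and 99.7 ± 1.25 CPM in KO2 (SD, n = 3), at least 2240-fold higher. EdgeR called 7400 genes, 3367 higher and 4033 lower, of which 2102 changed at least 2-fold (541 higher and 1561 lower). The higher share of the calls was 45.5%, and it was 35.8% under total count scaling (2652 higher and 4761 lower), 35.7% on log2(FPKM + 1) and 35.5% on log2(FPKM + 0.1). Total count scaling moved the median log2 fold change of all genes by -0.077.

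In KO2 the inflammatory list passed the test (camera adjusted p = 1.1e-38), also with an estimated correlation (adjusted p = 6e-04). Cxcl16 fell (log2 fold change -2.80) and Cx3cl1 rose (2.35). The interferon list passed as well (camera adjusted p = 7.76e-11), but not with an estimated correlation (adjusted p = 0.271). Its median log2 fold change was -1.84, with Trim30a at -5.43, Gbp2 at -4.05 and Gbp4 at -3.93, while Socs1 rose (0.53). On log2(FPKM + 1), where low levels are compressed, that median was -0.60. Adjusted over the list alone, 2 inflammatory genes were higher and 28 lower, and 2 interferon-stimulated genes were higher and 44 lower. Between the clones, 45 of the 49 interferon-stimulated genes and 32 of the 33 inflammatory genes differed (edgeR test of KO2 against KO1), and 15 and 7 were called in opposite directions. The 15 fell to 8 without Ctrl replicate 1, without Ctrl replicate 3 and without KO1 replicate 1.

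**Figure D2:**
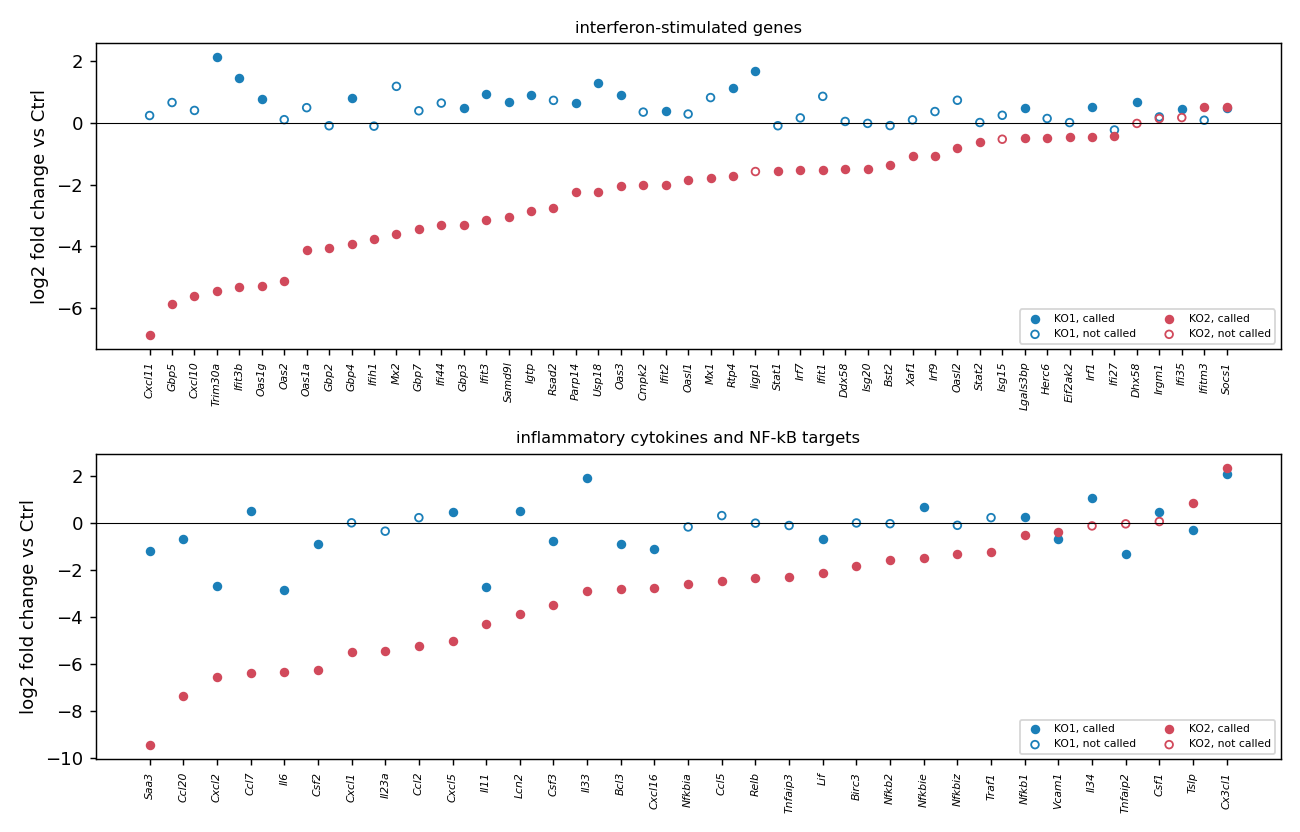
Log2 fold change against Ctrl (vertical axis) of each tested interferon-stimulated gene and each inflammatory gene, ordered by its value in KO2. Filled points passed edgeR at an adjusted p under 0.05 and open points did not. In KO2, 42 of 49 and 28 of 33 genes were lower, against 0 and 13 in KO1.

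Among the serpins in KO2, Serpina3f and Serpina1b had 0 counts and were at least 203-fold and at least 473-fold lower. Serpina3g kept 1 count, 0.0366% of the control (95% counting interval 0.000927% to 0.204%), and Serpine2 rose (log2 fold change 0.96). The list was called (camera adjusted p = 9.34e-13; adjusted p = 0.00249 with an estimated correlation), and the counts were unchanged when adjusted over the list alone. Of the 24 pyroptosis genes, 4 were higher and 10 lower in KO2 (camera adjusted p = 0.00296; adjusted p = 0.0828 with an estimated correlation). Camera on the gene statistics did not call it (adjusted p = 0.0787). The sensor genes Nod2 and Nlrp3 kept 3 counts each, 0.392% (95% counting interval 0.0807% to 1.15%) and 1.70% (0.347% to 5.03%) of the control. Naip6 had 0 counts and was at least 72.1-fold lower, and Naip5 fell (-3.22). Casp1 rose less than in KO1, with a log2 fold change of 0.29 (edgeR adjusted p = 0.00828). Gsdmd stood at 47.5 ± 2.07 CPM in Ctrl and 51.9 ± 3.18 CPM in KO2 (SD, n = 3; log2 fold change 0.13, edgeR adjusted p = 0.164), and its value was -0.03 on the FPKM scale with either pseudocount. The counts were 4 and 10 as well when adjusted over the list alone.

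Of the 23 checkpoint and NK or T cell ligands, 8 were higher and 9 lower in KO2 (camera adjusted p = 0.0136; adjusted p = 0.124 with an estimated correlation). Camera on the gene statistics did not call that list (adjusted p = 0.526). Cd274, which encodes PD-L1, fell from 1.74 ± 0.284 to 0.716 ± 0.0290 CPM (SD, n = 3; log2 fold change -1.28), and the death receptor gene Fas fell by 6.58 on the log2 scale. Icam1 (-8.49), Ptgs2 (-2.55), Tgfb2 (-4.47) and Nectin2 (-1.18) were lower as well. Of 28 genes of MHC class I presentation, 3 were higher and 7 lower, with Psmb8 (-0.75), Tap2 (-0.82) and Tapbp (-0.45) lower and B2m higher (0.32). Of the 11 Wnt ligands, 1 was higher (Wnt7b, 0.90) and 5 lower. Wnt9b had 0 counts and was at least 22.5-fold lower, and Wnt3 and Wnt6 kept 2.65% (95% counting interval 0.539% to 7.91%) and 1.76% (0.211% to 6.50%) of the control. Of 12 Wnt targets, 4 were higher and 4 lower, among them higher Tnfrsf19 (1.77), lower Tcf7 (-1.31) and Sfrp1 at 0 counts, at least 223-fold lower. Camera called neither the MHC list nor the Wnt lists. The median of the Wnt targets was 0.06 and their mean -0.93, which includes the fitted value of Sfrp1 and so depends on the prior count. Counts adjusted over the list alone were 9 and 9 (checkpoint), 2 and 7 (MHC), 1 and 5 (ligands) and 4 and 4 (targets).

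Cell cycle genes were higher in KO2, with 35 of 40 G2/M genes higher and 0 lower (camera adjusted p = 7.03e-07; adjusted p = 0.503 with an estimated correlation). Nusap1 (log2 fold change 0.86), Cdc25c (0.94), Kif23 (0.67) and Top2a (0.59) were examples. Of 39 G1/S and S phase genes, 25 were higher and 4 lower (camera adjusted p = 0.00676; adjusted p = 0.629 with an estimated correlation), with Rfc4 higher (0.55) and Ccne1 (-0.56), Ccne2 (-0.44) and Blm (-0.44) lower. Ribosomal protein genes were higher in 32 of 67 cases and lower in 1 (camera adjusted p = 0.000914; adjusted p = 0.543 with an estimated correlation), with Rpl24 at 1.42, Rps14 at 0.85, Rpl5 at 0.57 and Rplp2 at -0.27. Nuclear speckle and splicing factor genes were higher in 19 of 38 cases and lower in 2 (camera adjusted p = 0.0181; adjusted p = 0.547 with an estimated correlation), including Srsf6 (0.80) and Srsf2 (0.65). On the FPKM scale 12 of these were called in place of 21. Of 16 paraspeckle genes, 6 were higher and 2 lower, with Rbm3 at 0.58 and Pspc1 at -0.68, and camera did not call the list. Adjusted over the list alone, the counts were 35 and 1, 26 and 4, 32 and 1, 19 and 2, and 6 and 2 in that order.

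Of 26 NRF2 antioxidant genes, 15 were higher and 4 lower in KO2 (camera adjusted p = 0.00561; adjusted p = 0.529 with an estimated correlation), with Gstm1 at 1.32 on the log2 scale, Taldo1 at -0.64 and Hmox1 at -1.39. Of 20 p53 targets, 1 was higher and 11 lower (camera adjusted p = 0.00429; adjusted p = 0.207 with an estimated correlation), including Plk2 (-3.50), Mdm2 (-0.75) and Fas. Of 37 matrix genes, 7 were higher and 14 lower (camera adjusted p = 0.0142; adjusted p = 0.529 with an estimated correlation), with Timp2 (0.53), Col7a1 (1.01) and Col18a1 (0.86) higher and Dcn lower (-6.39). Camera on the gene statistics did not call the matrix list (adjusted p = 0.223). Of 18 epithelial genes, 6 were higher and 9 lower, with a list median of -0.41 and a mean of -1.05, and fry passed the list as lower (fry adjusted p = 5e-04). Krt18 (1.79), Krt8 (1.5) and Prss8 (0.61) were among those higher. Of 23 mesenchymal genes, 6 were higher and 12 lower, with Mmp9 (-2.27), Mmp13 (-0.43) and Tagln (-2.83) lower. Acta2 fell by 4.11 on the log2 scale, and the value was -6.72 without KO2 replicate 2. Of 25 stem and basal genes, 6 were higher and 12 lower, with Lgr6 higher (2.98) and Ly6a lower (-3.50). Krt14 had 0 counts and was at least 31.9-fold lower, and Krt17 kept 1 count, 0.490% of the control (95% counting interval 0.0124% to 2.76%). Of 24 YAP/TEAD targets, 9 were higher and 13 lower, with Itgb2 at 2.07, Arhgef17 at -1.20 and Ankrd1 at -0.62. Of 35 glycolysis and hypoxia genes, 3 were higher and 7 lower, with Aldoc at 1.61 and Ddit4 at -0.83. Of 24 cholesterol synthesis genes, 4 were higher and 5 lower, with Lss at -0.90, Sqle at -0.31 and Hsd17b7 at -1.35. Of 32 ATF4 targets, 2 were higher and 10 lower, with Chac1 at -0.84 and Stc2 at -2.98. Camera called none of the last 7 lists. In KO2, fry passed 23 of the 27 tested lists, and 27 when changes in either direction counted. Adjusted over the list alone, the counts were 15 and 5 (NRF2), 1 and 11 (p53), 7 and 14 (matrix), 6 and 9 (epithelial), 6 and 12 (mesenchymal), 6 and 12 (stem and basal), 9 and 13 (YAP/TEAD), 3 and 6 (glycolysis), 4 and 5 (cholesterol) and 2 and 10 (ATF4).

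Markers of other cell types in KO2 must be read beside KO2 replicate 2, in which lung, blood and connective tissue transcripts summed to 56.3 CPM, against at most 2.22 CPM in a control library. Of 5 fibroblast markers, 1 was higher (Pi16, log2 fold change 2.15) and 4 lower, including Dcn and Pdgfra (-1.0; camera adjusted p = 0.00676; adjusted p = 0.124 with an estimated correlation). Camera on the gene statistics did not call the fibroblast list (adjusted p = 0.0905). Of 5 macrophage and neutrophil markers, 1 was higher and 2 lower, and 1 was called without KO2 replicate 2. Mrc1 had 0 counts and was at least 33.0-fold lower. Of 3 endothelial markers, 1 was lower, Plvap (-1.99), and 2 were called without KO2 replicate 1. Pecam1 was at 2.05, not called, and at -0.61 without KO2 replicate 2, although it was called at 2.64 without KO2 replicate 1. Lck (-1.08) and Pparg (-2.17) were lower, as the 1 tested T and NK cell marker and 1 of 2 adipocyte markers; both adipocyte markers were called without Ctrl replicate 2. Of 9 imprinted genes, 1 was lower (Eif2s3x, -0.32), and 2 were called without Ctrl replicate 1 or KO2 replicate 3. Of 4 cancer-testis genes 2 were lower, Brdt (-1.66) and Rhox5, which kept 2.56% of the control (95% counting interval 0.305% to 9.51%). Adjusted over the list alone, the counts were 1 and 4 (fibroblast), 1 and 2 (macrophage), 0 and 1 (endothelial), 0 and 1 (T and NK), 0 and 2 (adipocyte), 0 and 1 (imprinted) and 0 and 2 (cancer-testis). Camera called neither the macrophage nor the imprinted list.

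**Figure D3:**
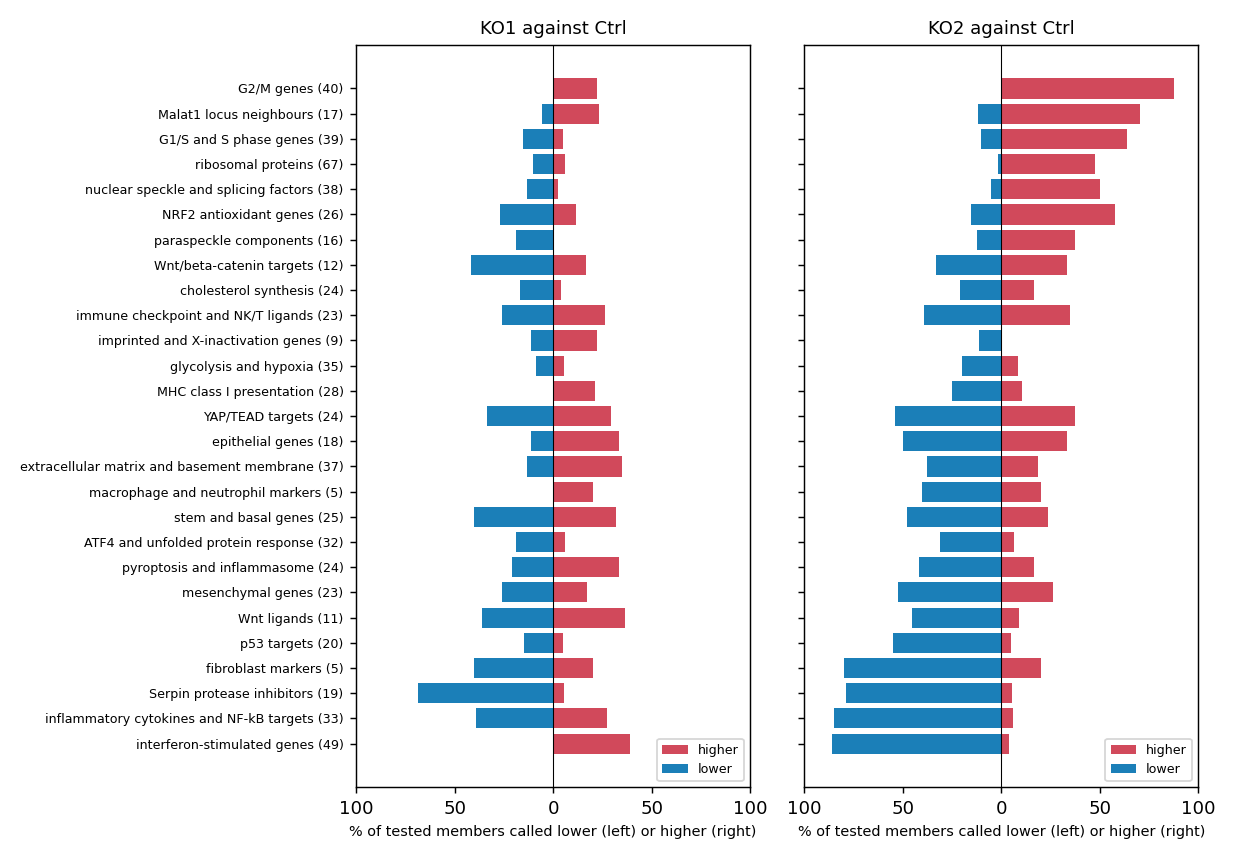
Share of the tested members of each list with at least 5 tested genes (number in brackets) that edgeR called lower (left, blue) or higher (right, red), in percent, for KO1 and KO2 against Ctrl. Serpins were lower in 13 of 19 cases in KO1 and 15 of 19 in KO2.

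What the clones had in common was asked next. Among the lists, serpins had the most members lower in both clones, 12 of 19, and 1, Serpine2, was higher in both. No list was tested for a shared change, and several of these serpins lie close together on chromosome 12, so linked genes may count as separate. Among the largest shared decreases, Stra6, a retinol transporter gene, stood at 20.4 ± 4.19 CPM in Ctrl (SD, n = 3), kept 1 count in KO1 (0.0490% of the control, 95% counting interval 0.00124% to 0.273%) and had 0 in KO2, at least 423-fold lower. Il2rg, the common gamma chain of interleukin receptors, fell by 7.28 in KO1 and 6.48 in KO2 on the log2 scale. Among the largest shared increases, Zfp523 rose from 0.460 ± 0.109 to 21.3 ± 0.954 CPM in KO1 and 31.8 ± 0.949 CPM in KO2 (SD, n = 3; log2 fold changes 5.52 and 6.09), and Sulf2 rose by 3.03 and 3.26. G2/M genes were higher in both clones in 8 of 40 cases and lower in both in 0, with 5 shared without Ctrl replicate 2 and without KO1 replicate 2.

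The other named shared increases were Rcan2 (log2 fold change 3.78 in KO1 and 3.83 in KO2), Chdh (3.96 and 3.76), Cplx2 (3.39 and 4.73), Bpifb4 (2.95 and 5.57), Prkcb (2.69 and 2.94), Cd300ld5 (2.73 and 7.31), Cd300ld4 (3.03 and 8.02) and Sgk2 (2.82 and 5.53). Without Ctrl replicate 3, Cd300ld4 was at 5.87 and 10.86 and Sgk2 at 3.90 and 6.61. Cd300ld4 and Cd300ld5 are close copies whose split is uncertain. The other named shared decreases were Serpina3f, Serpina3g and Serpina1b, given above, and Cd300lg, Sorcs1, Islr, Sirpa and Rims2. In KO1, Cd300lg kept 0.264% (95% counting interval 0.0544% to 0.773%), Sorcs1 0.328% (0.0396% to 1.19%), Islr 0.108% (0.00273% to 0.604%) and Rims2 0.336% (0.0406% to 1.22%) of the control, and Sirpa had 0 counts, at least 137-fold lower. In KO2, Cd300lg kept 0.294% (0.0606% to 0.863%) and Sorcs1 had 0 counts, at least 90.9-fold lower. Islr fell by 7.57, Sirpa by 6.51 and Rims2 by 6.39 on the log2 scale in KO2; without KO2 replicate 2 the first 2 values were -8.82 and -8.30, and without KO2 replicate 1 Rims2 was at -7.30.

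In all, 1934 genes were called in both clones in the same direction, 863 higher and 1071 lower, and 476 of them (142 and 334) changed at least 2-fold in both. Independent lists of these sizes would share 525.6 and 601.6 genes. Another 828 were called in opposite directions (543 higher in KO1 and 285 lower), where independent lists would give 1131.9. Across genes, which are not independent replicates, the fold changes of both clones had r = 0.32 and a covariance of 0.465, with the same sign in 59% of genes. Simulated groups without any effect, set against the same controls, gave a mean r of 0.50, a covariance of 0.026, the same sign in 66.4% of genes and at most 1 shared call. The observed r and share of genes with the same sign were thus below the simulated ones, and only the covariance and the shared calls were above. The difference in covariance was 0.439. It includes fitted values of genes with 0 counts in a group, which depend on the prior count, such as -11.21 for Serpina3f in both clones. The 3 controls could not be split into sets of at least 2, so part of the excess may come from the shared controls.

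**Figure D4:**
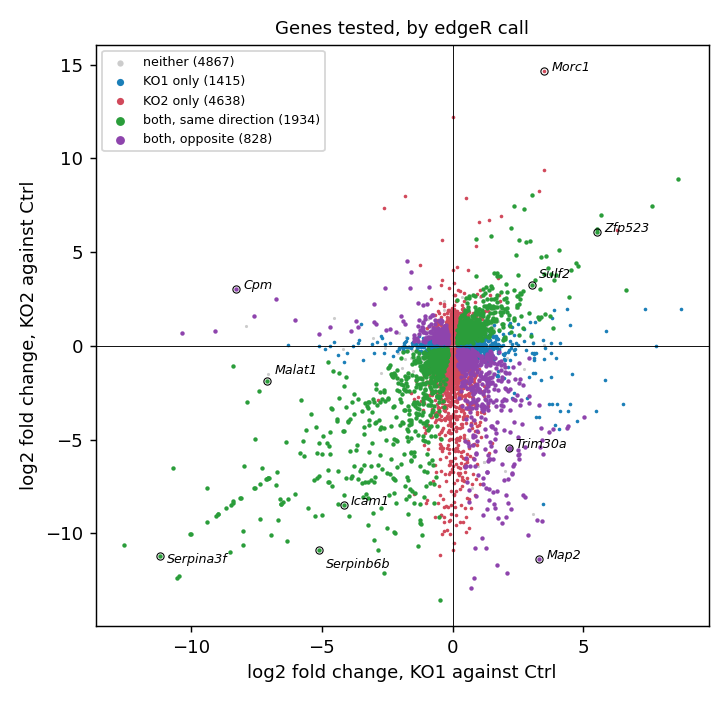
Log2 fold change of each of 13682 tested genes against Ctrl in KO1 (horizontal axis) and KO2 (vertical axis), coloured by the edgeR call in each clone, with counts in the key. Of the genes, 1934 were called in both in the same direction and 828 in opposite ones. Fitted values of genes with 0 counts in a group depend on the prior count and are no bounds.

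The direct comparison of KO2 with KO1 asked where the clones differed from each other. Map2, which encodes a microtubule-associated protein, stood at 10.2 ± 0.948 CPM in Ctrl, 101 ± 2.58 CPM in KO1 and 0 in KO2 (SD, n = 3), at least 1570-fold lower in KO2 than in KO1 and at least 158-fold lower than in Ctrl. Sfrp1 (at least 718-fold), Nipal2 (at least 675-fold), the metalloreductase gene Steap4 (at least 658-fold) and the growth factor gene Pdgfc (at least 425-fold) were likewise at 0 counts in KO2. Against Ctrl, Nipal2, Steap4 and Pdgfc were at least 380-fold, at least 917-fold and at least 45.4-fold lower in KO2, while their log2 fold changes in KO1 were 0.83, -0.48 and 3.22, and that of Map2 was 3.31. In the other direction, Cpm, a carboxypeptidase gene, had 0 counts in KO1 and was at least 177-fold higher in KO2 and at least 21.7-fold higher in Ctrl. Ube2ql1 kept 2 counts in KO1, 0.0390% of its level in KO2 (95% counting interval 0.00472% to 0.141%) and 0.0636% of that in Ctrl (0.0077% to 0.230%).

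Ogdhl and Sall2 kept 1 count each in KO1, 0.0783% (95% counting interval 0.00198% to 0.437%) and 0.118% (0.00299% to 0.662%) of their level in KO2, and 0.134% (0.00339% to 0.749%) and 0.675% (0.0170% to 3.82%) of that in Ctrl. Morc1 was at 0.0410 ± 0.0467 CPM in KO1 (SD, n = 3), against 99.7 CPM in KO2. Against Ctrl, the log2 fold changes in KO2 were 3.03 for Cpm, 0.71 for Ube2ql1, 0.78 for Ogdhl and 2.51 for Sall2. EdgeR called 7529 genes between the clones, 3495 higher and 4034 lower in KO2, of which 2172 differed at least 2-fold (514 and 1658). The higher share was 46.4%, and it was 33.4% under total count scaling, 33.7% on log2(FPKM + 1) and 33.2% on log2(FPKM + 0.1). Total count scaling moved the median of all genes by -0.106 in this comparison, and values here are relative to TMM scaling. Of the genes called against Ctrl in KO1 alone, 1130 of 1415 differed between the clones, as did 3718 of 4638 called in KO2 alone and 873 of the 1934 shared ones.

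The genotype label joins both clones, and their mean was compared with Ctrl last. Serpinb6b was lower and Serpine2 higher in both clones, but each differed between them (edgeR test of KO2 against KO1, log2 fold changes -5.75 and -0.22). Interferon-stimulated genes moved apart, with 19 of 49 higher in KO1 and 42 lower in KO2, so their mean described neither clone. Casp1 rose in both, by 0.95 in KO1 and 0.29 in KO2, and also differed between them (log2 fold change -0.66). For the mean, edgeR called 5793 genes, 2512 higher and 3281 lower, of which 1295 changed at least 2-fold (310 and 985). The 6 knockout libraries come from 2 lines.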

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

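The comparisons against Ctrl and of KO2 with KO1, with their list tests, were planned, and the tests on lost chromosome segments and on other splits of the samples were chosen before their results were seen. The other tests in this part were chosen after. No group held 4 or more samples, so no test for a single sample far from its group was run. Genes raised in 1 library alone were counted instead and are given with the third pattern.

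The clones differed from each other, by the edgeR test of KO2 against KO1, in 84 of the 128 genes reported, of which 46 were lower and 38 higher in KO2. Of all 13682 tested genes, 7529 (55%) differed. The rule for named genes took 5 per direction for such a difference and list members by their adjusted p. The 84 are thus a count over selected genes. Values in this part are log2 fold changes of KO2 against KO1. For Map2 (-10.61), Sfrp1 (-9.49), Nipal2 (-9.40), Steap4 (-9.36), Pdgfc (-8.73), Mrc1 (-4.61) and Naip6 (-3.18), with 0 counts in KO2, and for Cpm (7.47) and Sirpa (0.52), with 0 in KO1, they are bounds from the floor of 3 counts. Fitted values of genes with 1 to 3 counts in a clone depend on the prior count. Of the level in KO1, KO2 kept 13.9% of Serpina3g (95% counting interval 0.314% to 104%, which includes no difference), 1.58% of Serpinb6b (0.19% to 5.82%), 1.84% of Nod2 (0.376% to 5.46%) and 1.32% of Rhox5 (0.159% to 4.84%), and KO1 held 2.49% of the Stc2 level in KO2 (0.0614% to 14.8%). Those of Ube2ql1, Ogdhl and Sall2 are in the comparison of the clones.

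Genes lower in KO2, chosen by the rule for named genes, included Saa3 (-8.27), Trim30a (-7.57), Fas (-6.55), Nod2 (-5.61), Gbp4 (-4.73), Icam1 (-4.33), Gbp2 (-3.97), Tgfb2 (-3.54), Csf3 (-2.70), Cxcl16 (-1.68), Cd274 (-1.54), Naip5 (-1.52), Tap2 (-0.91), Psmb8 (-0.84), Tapbp (-0.83), Nectin2 (-0.72), Casp1 (-0.66), Ptgs2 (-0.61) and Rela (-0.52). Serpins were lower as well, namely Serpinb6b (-5.75), Serpina3g (-2.48) and Serpine2 (-0.22). The remaining lower genes were Rhox5 (-6.01), Dcn (-5.13), Fabp4 (-4.57), Plk2 (-2.95), Brdt (-2.51), Pparg (-2.45), Cd68 (-1.31), Lck (-1.22), Aldoc (-1.0), Lss (-0.91), Sqle (-0.89), Pdgfra (-0.87), Pspc1 (-0.86), Cdc42ep2 (-0.75), Hmox1 (-0.68), Mdm2 (-0.40) and Mmp9 (-0.40). Without 1 library the call was lost for Serpina3g (-2.12 without KO1 replicate 1, -2.01 without KO2 replicate 1, -2.03 without KO2 replicate 2; -4.46 and called without KO2 replicate 3), Aldoc (-0.84 without KO2 replicate 1) and Mmp9 (-0.34 without KO2 replicate 2).

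Genes higher in KO2 included Malat1 itself (5.21) and its neighbours Frmd8 (0.94), Neat1 (0.90), Ltbp3 (0.88) and Slc25a45 (0.79). Others were Morc1 (11.15), Ube2ql1 (11.07), Ogdhl (9.85), Sall2 (9.25), Cd300ld4 (4.99), Stc2 (4.87) and Cd300ld5 (4.58). Without KO1 replicate 3, Morc1 was at 12.38 and Sall2 at 11.09, and without KO1 replicate 1, Ogdhl was at 11.68 and Stc2 at 6.70. Further genes were Sgk2 (2.70), Bpifb4 (2.62), Lgr6 (1.61), Rpl24 (1.34), Cplx2 (1.34), Itgb2 (1.20), Mmp13 (1.07), Rps14 (0.86), Krt18 (0.85), Krt8 (0.73), Srsf6 (0.72), Rbm3 (0.70), Srsf2 (0.66), Tnfrsf19 (0.60), Eng (0.59), Zfp523 (0.58), Cdc25c (0.55), Nusap1 (0.54), Ankrd1 (0.47), Gstm1 (0.39), Wnt7b (0.34), Col18a1 (0.27), Rfc4 (0.23) and Gsdmd (0.22). Calls lost without 1 library were those of Gsdmd (0.20 without KO1 replicate 1 or 3, 0.22 without KO2 replicate 1, 0.18 without KO2 replicate 2), Col18a1 (0.29 without KO1 replicate 3, 0.28 without KO2 replicate 2, 0.24 without KO2 replicate 3) and Wnt7b (0.28 without KO2 replicate 3). Gstm1 was not called without Ctrl replicate 1 (0.39), Ctrl replicate 3 (0.39), KO1 replicate 1 (0.22), KO1 replicate 3 (0.41) or KO2 replicates 1 (0.37), 2 (0.43) and 3 (0.36). Sirpa was not called without any 1 of the 9 libraries except KO2 replicate 1, with edgeR adjusted p between 0.0514 and 0.236 in the 8 other cases.

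Among the lists, 13 differed between the clones by camera. The adjusted p of camera was 1.89e-32 for inflammatory genes, 5.16e-17 for interferon-stimulated genes, 0.000878 for pyroptosis, 0.00101 for matrix, 0.00343 for epithelial genes, 0.0114 for fibroblast markers and 0.0141 for p53 targets, all lower in KO2. It was 0.000414 for ribosomal proteins, 0.00056 for G1/S and S phase genes and also 0.00056 for NRF2 genes, 0.000729 for G2/M genes, 0.0104 for nuclear speckle genes and 0.0393 for the Malat1 neighbours, all higher in KO2. With an estimated correlation only the inflammatory list passed (camera adjusted p = 0.00103). Fry passed 22 of the 27 tested lists in this comparison.

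The first pattern weighed was the Malat1 left in KO2, 27.2% of the control. Control cells mixed into the KO2 samples would bring every abundant control transcript at that share or more. The tables argue against this as the whole cause, since 331 of 10655 genes at 5 CPM or more in Ctrl had an upper 95% limit in KO2 below 27.2%, and 18 of them had 0 counts. RNA of another tissue in KO2 replicate 2 is argued against by the KO2 library with the least Malat1, which still held 21.2% of the control. A deletion that left part of the gene or an allele was not tested and stays open.

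The second pattern was the interferon and inflammatory genes, lower in KO2 and in part higher in KO1. For the interferon-stimulated genes, a response that grows as Malat1 falls is argued against as the whole cause. KO1 had less Malat1 and a median of 0.48, against -1.84 in KO2. For the inflammatory genes such a response was not tested apart. Their medians were -0.11 in KO1 and -2.61 in KO2, and 11 of 33 were lower in both clones. Each level of Malat1 was seen in a single line, so level and line cannot be told apart. Loss in KO2 of the chromosome segments that hold the interferon and inflammatory genes was checked on 70 of them on 16 chromosomes. Their 50 nearest genes outside both lists had a typical median of -0.07 (range -0.31 to 0.41), against -2.68 for the genes themselves. This argues against lost segments wide enough to hold most of those 50 genes. The test does not cover shorter lost segments at these genes, which would not move such a median, or lost segments elsewhere in the genome. Scaling is argued against by 3 other scalings of the counts, whose highest median was -1.82; this test was limited to scalings of counts after log2(FPKM + 1), which compresses low levels, had given -0.60. A difference between the clones that arose apart from Malat1 was not tested and stays open.

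The third pattern was in transcripts of which most were too low to test. Markers of lung, blood and connective tissue summed to 56.3 CPM in KO2 replicate 2, against at most 2.22 CPM in a control library and 5.30 CPM in any other library. Sftpc stood at 9.29, Hba-a1 at 7.56, Hbb-bs at 7.39, Eln at 4.75 and Scgb1a1 at 2.78 CPM. RNA of lung tissue is a candidate source. Of 28 such markers, 15 were at least 5 times higher in KO2 replicate 2 than in each other library, at about 5 counts or more. Of 42 markers of other tissues, 1 was (Trf). This test was chosen after the data had been seen, so part of the share may be built in. Another library of the series as the source is argued against, since lung markers summed to at most 3.87 CPM elsewhere and 21.2 CPM here, and a mixture cannot exceed its source; this bound was set after the value was seen. Only 4 of the 28 markers were tested, and the 89 genes more than 5 times above the other KO2 libraries (7 to 39 such genes in each other library against its own group) held 109 CPM and 7 of the 7400 KO2 calls (1 higher and 6 lower). No biological explanation was tested.

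Other splits of the same samples were counted for each comparison. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05; only the real one gave as many calls (1 of 10), with 4177 against at most 1 in another split for KO1, 7400 against 0 for KO2 and 7529 against 0 for KO2 against KO1. For the mean of the clones, 3 of 100 drawn splits gave 5793 calls or more, with 6515 as the highest other, and for the shared calls 3 of 100 gave 1934 or more, with 4411 as the highest other. The highest other split set the KO2 libraries as the control group in both cases, which points to a structure of the samples, KO2 lying apart from the rest. Splits that mix the 3 lines also widen the spread within groups, so these counts do not show that the grouping into control and knockout lies beyond chance.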

How the results depend on the processing

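All alternatives were planned. Of the recomputed values of named genes against Ctrl, and of the 10 genes with the largest difference between the clones, 4708 kept their direction and side of the threshold, 7 newly passed it and 3 reversed. For the other genes, calls of KO2 against KO1 were recomputed only without each library; those lost are given with the genes above, and fry was run only with all libraries. Of counts per list, 1287 stayed within 1.5 times and 73 did not, and of list tests 385 kept their side, 12 newly passed and 3 no longer did. The 12 were, in KO2, pyroptosis (no filter, DESeq2, without Ctrl replicate 2, without KO2 replicate 2), checkpoint ligands (DESeq2) and fibroblast markers (DESeq2, without KO2 replicate 2), at adjusted p of camera from 0.0184 to 0.0459, and the 5 of the MHC, G1/S and cholesterol lists in KO1 given above. The 3 were those of the G2/M list in KO1. Other scalings, filters, tools and units kept each of the 5 call counts within 1.5 times and Malat1 called lower in both clones. At an adjusted p of 0.01 (a stricter threshold), 2620 genes were called in KO1, 3808 for the mean of the clones and 1121 in both. With a minimum of 2-fold, the counts were 1083 (KO1), 2102 (KO2), 2172 (KO2 against KO1), 1295 (mean) and 476 (shared). Without each library in turn, they ran from 3215 to 4503, 6412 to 7985, 6451 to 7964, 4544 to 6474 and 1509 to 2349, and Malat1 from -7.19 to -6.93 in KO1 and from -2.09 to -1.72 in KO2.

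The reversed values were those of Gsdmd in KO2, -0.0329 on log2(FPKM + 1) and -0.0341 on log2(FPKM + 0.1), and of Pecam1 in KO2, -0.6094 without KO2 replicate 2. Pecam1 newly passed, in the same direction, without KO2 replicate 1 (2.6376). The cause was not tested for Gsdmd, and neither gene was called in KO2 against Ctrl with all libraries. B2m in KO1 newly passed under total count scaling (0.243), DESeq2 (0.2144), both FPKM fits (0.2415 and 0.2418) and without Ctrl replicate 2 or KO1 replicate 1. With a replicate block, the interferon-stimulated genes called in KO1 were 11 in place of 19; the cause was not tested. Before the values were limited to those the text reports, 9173 had been recomputed, of which 45 of named genes and 26 list tests reversed, 0 of them past the threshold with all libraries. With all libraries, camera on the gene statistics did not call 4 lists in KO2 that camera on counts called: pyroptosis (0.0787), checkpoint ligands (0.526), matrix (0.223) and fibroblast markers (0.0905). Depth limited folds of genes with 0 to 3 counts in a group to bounds or wide intervals.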

Other observations

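All tests in this part were chosen after the data had been seen, and none was planned. Gene Ontology terms of 10 to 500 genes (1454 terms, background of 9857 genes) were tested for sets of genes changed at least 2-fold in both clones or called in opposite directions. Only genes with an annotated process were used. Among the 243 such genes of the 334 lower in both, 11 terms passed. Acute-phase response held 8 of 16 members (adjusted p = 1.92e-06 by the hypergeometric test), namely Hp, Il1rn, Il6, Orm1, Saa1, Saa2, Saa3 and Serpina1b. Cellular response to lipopolysaccharide held 12 of 93 (hypergeometric adjusted p = 0.00132) and inflammatory response 13 of 138 (hypergeometric adjusted p = 0.00837). Negative regulation of endopeptidase activity held 4 of 14, namely Lrp2, Serpinb6b, Serpinb9 and Serpinb9b (hypergeometric adjusted p = 0.0432). For genes higher in KO1 and lower in KO2 (385 annotated of 543), 2 terms passed, of which cellular response to interferon-beta held 8 of 34 (hypergeometric adjusted p = 0.0272). For genes higher in both, and for genes lower in KO1 and higher in KO2, 0 terms passed.

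Blocks of 50 neighbouring genes were compared with random blocks (221 blocks, 11555 genes, 50000 permutations, 2e-05 being the smallest p they can give). In KO1, 74 blocks were shifted (30 up and 44 down), in KO2 68 (31 up and 37 down), and 19 in both in the same direction. On chromosome 12, all 8 blocks were lower in KO1, with medians from -0.712 to -0.255 and a chromosome median of -0.39, against -0.08 in KO2. Every block of chromosome 13 was also lower in KO1 (chromosome median -0.2, and -0.2 in KO2). Chromosome 7 had a median of -0.19 in KO1 and -0.13 in KO2. The chromosome 13 block that spans Serpinb6b was at -0.272 in KO1 and -0.265 in KO2. The chromosome 19 block that spans Malat1 was at 0.367 in KO2 (permutation adjusted p = 0.000295) and at 0.042 in KO1 (permutation adjusted p = 0.436). In KO2, chromosome 4 had a median of -0.31 and chromosome 18 of 0.24. The block with -0.712 holds the Serpina genes. Other genes beside them were lower in KO1, such as Ddx24 (-0.84), Ubr7 (-0.77), Glrx5 (-0.72) and Dicer1 (-0.58), while Asb2 was higher (4.38). In KO2, Ddx24 was at -0.05, Ubr7 at -0.03 and Dicer1 at 0.03, while Otub2 (-1.45), Tmem251 (-0.74), Itpk1 (-0.55) and Ifi27 (-0.42) were called lower. Asb2, at 0.313 CPM in Ctrl, was also called lower in KO2 (-4.4), and Syne3 (0.37) and Snhg10 (0.73) were called higher. DNA copy number was not measured in these libraries.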
